A study of Arabidopsis thaliana with 30 samples.

How the data were processed

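Total RNA of 30 Arabidopsis samples was labelled with Cy3 and hybridised to single-colour Agilent arrays. Per the labels' protocols, 150 ng of RNA with an integrity number of at least 7.5 was amplified and 1.65 µg of labelled cRNA was hybridised. Per the file headers, the authors extracted the spots with Agilent Feature Extraction 10.7.1.1 and the protocol GE1_107_Sep09, and the deposited scanner tables hold a background-corrected processed intensity for each spot, with flags for spots well above background, saturated or outlying. The authors' series table of values is also an intensity and was equal to the processed signal in all 30 columns, so it is linear, uncentred and unscaled, with column medians of 259 to 1006. The array build named in the headers differs from the TAIR10.1 assembly of the reference table, which was used for names only, and no coordinates are given.

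Each array held 45220 spots, 1417 of them control spots. Control spots and outlier-flagged spots (3 to 30 per array) were left out, no spot was saturated, and spots of a probe were averaged. The log2 processed signal less each array's own 75th percentile is called the scaled log2 signal. Of 43603 probes, 34285 were paired with a locus through an unversioned RefSeq accession and 9318 were not. Of 25383 loci, those with their probe well above background on both arrays of at least 1 group were tested, which left 22007 genes. The probe with the highest mean stood for its gene. Among 6329 genes with over 1 probe above background, 150 had probes called in opposite directions under salt and 59 under PEG.

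Groups were accession and treatment as the labels give them, with 2 arrays in each of 15 groups. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all arrays (15 residual degrees of freedom, 1.82 prior degrees of freedom), with moderated tests of contrasts and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p below 0.05. Salt, PEG and their difference were tested as means over the 5 accessions and, for salt and PEG, within each accession. Moderated F-tests took the accession by treatment interactions and the accession differences in control. The labels call the samples biological replicates, so the p-values measure the spread between such samples. The C24 control pair, of which the Results put 1 array in doubt, is part of this shared spread in every comparison. Each standard error comes from this fit, so it holds the spread between replicates of a group and not the spread of effects between accessions.

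The 29 gene lists (518 members, 3 of them without a probe and 1 dropped for a name that belonged to another gene) were fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for naming genes. The lists cover ABA and dehydration effectors, ABA metabolism, ABA signalling, CBF/DREB and ZAT regulators, proline metabolism, raffinose and soluble sugars, ion transport, aquaporins, photosynthesis, leaf senescence, jasmonate, salicylic acid and defence, ethylene, heat shock, antioxidant and ferritin, flavonoid and anthocyanin, glucosinolate biosynthesis, cell wall expansion, auxin response, cell cycle and DNA replication, circadian clock, phosphate starvation, iron deficiency, hypoxia and nitrate assimilation. Root, guard cell and stomatal lineage, vascular and floral lists stand for other organs and cell types. Lists with at least 5 members were tested with camera against the other genes at a preset correlation of 0.01, adjusted over the 29 lists of a comparison. An estimated correlation and fry, which asks whether a list's genes move one way on balance, were alternatives.

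List members and the genes always given apart, only loci with a symbol other than their locus code were eligible for naming. These held 14408 of the 34285 probes with a locus. Genes were named by rule. For each mean comparison these were the 6 largest rises and the 6 largest falls among genes called, of one direction in all accessions and above background on at least 8 of 10 arrays of both treatments, the 3 called members of each list with the largest change (or 2 where none was called; fewer are printed), and the 3 largest bounds. RD29A, RD29B, RAB18, NCED3, P5CS1, SOS1, HKT1 and NHX1 are always given. The rule also takes the largest rise and fall in each accession and treatment, the 5 smallest p of each F-test, and the 4 genes on each side that parted salt and PEG most. A few list members outside the rule (such as CBF3 under salt) were added after their values were seen.

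The 30 arrays lay on 8 slides scanned on 4 days, and slide and scan day each held several groups, so both were fitted as blocks and the means were refitted within the days that held 12 arrays. Alternatives were quantile normalization, normexp background correction (offset 50) on the median signal and median background because the tables used hold no mean signal, the authors' series table, no filter or all arrays above background, the mean of a gene's probes, an intensity trend, array weights, replicate blocks, leaving out each array or accession, only the groups compared, a 2-fold minimum, and both other list tests. Added after seeing the data were probes without a locus, values of single genes and lists without the array labelled C24 control replicate 1, and camera for 1 accession against the mean of the others.

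The fit was tested on simulated data drawn with the measured spreads of 21960 genes around accession means without treatment effects, with known changes added. For salt as a mean over accessions, 82.1%, 94.0% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered. Within Col the shares were 41.8%, 91.0% and 87.9%, and for an interaction in Ws alone 11.9%, 53.7% and 87.9%. Of 21560 unchanged genes 22, 8 and 4 were called, and of 29 lists the 1 shifted list was called and 0 of the 28 others. The simulated noise was independent between genes, whereas the estimated correlation within the real lists reached 0.82 (photosynthesis). Most simulated genes were unchanged, whereas 80.2% of the real genes were called under salt. These shares and list calls therefore need not carry over to the data.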

Results

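Gene expression was measured on 30 single-colour Agilent arrays of Arabidopsis thaliana, with 1 RNA sample per array. Plants of 5 natural accessions (C24, Col, Ler, Sha and Ws) received a control treatment, 100 mM NaCl (salt, which brings sodium and chloride ions and lowers the water potential) or polyethylene glycol (PEG, a large solute that lowers the water potential without adding those ions). Each of the 15 groups held 2 biological replicates, and each sample pooled at least 30 seedlings. The title of the series sets osmotic against ionic responses, and the comparisons below follow that question. The labels disagree on details: the PEG potential is −1.2 MPa in one label and −0.7 MPa in another, the treatment lasted 4 days or 48 h, and the material is called whole seedling in one place and leaves in another. They give a start of treatment at 10 days of age and an age of 2 weeks for all samples. The labels do not show whether the salt and PEG doses were matched, so the sizes of both responses are given side by side without ranking the treatments per dose. The 75th percentile of the processed signal lay between 1534 and 6096 units over the arrays, between 72.5% and 79.0% of the spots were well above background, and the number of arrays limits the precision.

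The array labelled C24 control replicate 1 stood apart from its group. Across genes, which are not independent replicates, its log2 signals correlated at 0.944 with C24 control replicate 2 and at 0.993 and 0.994 with the Ler controls. Replicates of the other groups correlated at 0.992 to 0.996. It was kept in its labelled group, so 1 of the 2 arrays behind each C24 control mean is in doubt, and values without it stand beside the leading counts. The SD of the replicate difference over genes was 1.08 for the C24 controls and 0.31 to 0.43 in the other groups. The fit shares the spread over all groups, so this difference also enters the errors and p-values of comparisons without C24 control arrays.

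**Figure D1:**
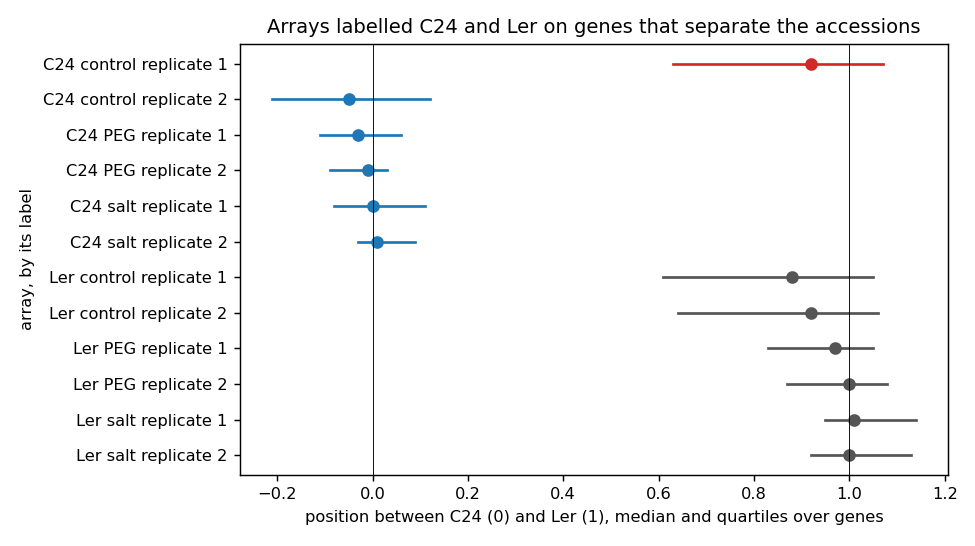
Position of the 12 arrays labelled C24 or Ler between C24 (0) and Ler (1) on the genes that separate these accessions, as median (point) and quartiles (line) over genes. The array labelled C24 control replicate 1 (red) lies at 0.92, beside the Ler arrays at 0.88 to 1.01, and the other C24 arrays lie at −0.05 to 0.01; the replicate 2 PEG and salt arrays set the scale and chose the genes, so their positions are fixed by construction.

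Salt raised genes of the abscisic acid (ABA) and dehydration response in all accessions. Over the 5 accessions LTP4, a lipid transfer protein gene, rose by 11.11 ± 0.24 on the log2 scale (SE, n = 10 arrays per treatment), RD29B and LEA4-5, which encode dehydration-induced protective proteins, rose by 7.58 ± 0.27 and 7.58 ± 0.18, and the dehydrin gene RAB18 by 5.25 ± 0.15. These errors, here and below, hold the spread between replicates and not that between accessions. The rise of LTP4, for example, was 9.34 in Ws and 11.79 in Sha. LTP4, RD29B and LEA4-5 were well above background on 9 of the 10 control arrays. For RD29B the remaining array was C24 control replicate 2, so its detection in C24 controls rests on the array labelled C24 control replicate 1. Without that array RD29B rose by 7.91 over the accessions. Its rise in C24 was 7.71 with that array and 9.35 without it, the latter against a single control array not well above background. RD29A rose by 5.18 ± 0.22, CSLG2, a cellulose synthase-like gene, by 8.66 ± 0.19 and TSPO, a stress-induced membrane protein gene, by 7.56 ± 0.30. All 32 measured ABA and dehydration effectors were called higher, 30 of them at least 2-fold, with a median change of 3.5 (camera adjusted p = 6.56e-15, and adjusted p = 0.0574 with an estimated correlation). Among 26 ABA signalling genes 18 rose and 8 fell (median 1.01, camera adjusted p = 0.00865, and adjusted p = 0.0555 with an estimated correlation). The protein phosphatase genes HAI1 and HAI3, negative regulators of ABA signalling, rose by 6.48 ± 0.16 and 6.57 ± 0.12, while the receptor gene PYL6 fell by 4.28 ± 0.07. ABA metabolism followed with 9 of 13 higher and 3 lower (median 0.96, camera adjusted p = 0.0194, and adjusted p = 0.18 with an estimated correlation): NCED3, the main stress-induced gene of ABA synthesis, rose by 4.34 ± 0.11 and CYP707A1, which degrades ABA, by 3.71 ± 0.11.

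Proline metabolism, stress regulator, heat shock and flavonoid lists were also higher under salt. P5CS1, which encodes the committed step of stress-induced proline synthesis, rose by 3.5 ± 0.04 and OAT by 1.52 ± 0.04, and 7 of 9 proline metabolism genes were higher (median 1.28, camera adjusted p = 0.00257, and adjusted p = 0.0555 with an estimated correlation). DREB2B rose by 3.70 ± 0.09 and CBF3 by 3.29 ± 0.04 within the CBF/DREB and ZAT regulators, of which 8 of 9 rose and RAV1 fell (median 3.10, camera adjusted p = 0.000751, and adjusted p = 0.24 with an estimated correlation). All 21 heat shock genes rose, 19 at least 2-fold (median 2.35, camera adjusted p = 1.71e-09), including the transcription factor gene HSFA2 at 3.84 ± 0.05. PAP1 and UF3GT, a regulator and an enzyme of anthocyanin synthesis, rose by 4.33 ± 0.05 and 3.08 ± 0.11, with 13 of 19 flavonoid and anthocyanin genes higher and 4 lower (median 2.00, camera adjusted p = 0.000746). Leaf senescence genes were higher in 12 of 13 cases (median 1.35, camera adjusted p = 0.000278, and adjusted p = 0.18 with an estimated correlation), led by SAG13 at 5.03 ± 0.20 and DIN2 at 4.14 ± 0.13.

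The jasmonate, ethylene, phosphate starvation and hypoxia lists were higher under salt as well. Of 27 jasmonate genes 23 rose and 3 fell (median 1.67, camera adjusted p = 2.3e-07): JAZ7, a repressor of jasmonate signalling that jasmonate itself induces, rose by 4.25 ± 0.06, while the defensin genes PDF1.2A and PDF1.2B fell by 2.80 and by 2.58. Ethylene genes were higher in 11 of 14 cases (median 1.08, camera adjusted p = 0.000367), with the synthesis gene ACS2 up by 4.68 ± 0.09 and the response factor gene ERF1 by 5.23 ± 0.03. Among 14 phosphate starvation genes 12 rose, among them RNS1 (4.54 ± 0.06) and SPX3 (3.22 ± 0.13), and 2 fell (median 1.39, camera adjusted p = 0.000592, and adjusted p = 0.18 with an estimated correlation). Hypoxia genes were higher in 7 of 12 cases and lower in 2 (median 0.29, camera adjusted p = 0.0322, and adjusted p = 0.0741 with an estimated correlation), with ADH1, alcohol dehydrogenase, up by 3.94 ± 0.04.

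Iron uptake genes, root markers and growth genes fell under salt. IRT1, the iron transporter of the root epidermis, fell by 5.81 ± 0.06, CYP82C4, a cytochrome P450 of the iron deficiency response, by 5.93 ± 0.29 and NAS2, a nicotianamine synthase gene, by 4.48 ± 0.08, and 10 of 13 iron deficiency genes were lower (median −1.84, camera adjusted p = 0.0171, and adjusted p = 0.468 with an estimated correlation). All 14 root markers fell (median −1.37, camera adjusted p = 2.89e-05), among them the Casparian strip gene CASP1 (−2.28 ± 0.04). Cell cycle and DNA replication genes were lower in 22 of 23 cases (median −1.16, camera adjusted p = 3.66e-07), with PCNA1, the replication clamp, down by 1.58 on average (−1.58 ± 0.04). Cell wall expansion genes fell in 15 of 20 cases (median −0.78, camera adjusted p = 0.00692), led by the expansin gene EXPA8 at −4.23 ± 0.16, whereas EXPA10 rose by 3.62 ± 0.08. GASA6, a gibberellin-regulated peptide gene, was lower by a log2 change of −4.56 ± 0.06 and the cytochrome P450 gene CYP712A1 by −5.59 ± 0.05. Its relative CYP712A2 fell by 5.29 ± 0.43, with 8 of 10 salt arrays above background.

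Photosynthesis and glucosinolate genes were lower under salt too. Of 45 photosynthesis genes 33 fell and none rose (median −0.73, camera adjusted p = 0.000456, and adjusted p = 0.538 with an estimated correlation), with the light-harvesting gene LHCB2.4 at −2.85 ± 0.08. Of 21 glucosinolate genes 18 fell (median −1.17, camera adjusted p = 0.000438, and adjusted p = 0.18 with an estimated correlation), including MYB28, a regulator of the aliphatic branch, at −2.02 ± 0.04 and CYP79F2 at −3.16 ± 0.13. Aquaporin genes were lower in 14 of 19 cases (median −0.65, camera adjusted p = 0.0198, and adjusted p = 0.468 with an estimated correlation), with PIP2;4 at −2.03 ± 0.04 and PIP2;5 higher by 2.00 ± 0.11.

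The ion transport list as a whole was not called (14 of 31 higher, 16 lower, median −0.18, camera adjusted p = 0.882), yet single members moved far. NRT1.8, which takes nitrate out of the xylem, rose by 7.93 ± 0.12. HKT1, which retrieves sodium from the xylem, was not well above background on any of the 10 salt arrays and was at least 11.2-fold lower than in control. The anion channel gene SLAH1 was at least 9.10-fold lower by the same measure. SOS1 and NHX1, the sodium/proton antiporter genes of the plasma membrane and the vacuole, rose by 0.32 ± 0.09 and 0.88 ± 0.04. The largest bounds belonged to NRT2.6, a nitrate transporter gene at least 133-fold higher, DDF1, a DREB-type regulator gene at least 32.8-fold higher, and GRP20 at least 21.6-fold lower, out of 157 named genes called while all arrays of 1 of the treatments lay below that limit. A bound sets the bright treatment's mean against the mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background.

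The remaining lists were not called under salt. Salicylic acid and defence genes were higher in 14 of 22 cases and lower in 7 (median 0.38, camera adjusted p = 0.0764). In the same order, raffinose and soluble sugar genes gave 7 and 4 of 13 (0.81, camera adjusted p = 0.0874), with GOLS2 at 4.56 ± 0.09. Circadian clock genes gave 11 and 5 of 17 (0.43, 0.0575) and antioxidant and ferritin genes 6 and 5 of 15 (0.13, 0.709). Auxin response genes were higher in 3 and lower in 9 of 15 cases (−0.97, 0.296), nitrate assimilation genes in 1 and 5 of 7 (−1.10, 0.0715). Guard cell and stomatal lineage markers gave 2 and 9 of 12 (−0.33, 0.0757), vascular markers 2 and 5 of 8 (−0.44, 0.326) and floral regulators 2 and 4 of 9 (−0.19, 0.565).

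Of 22007 genes tested, 8038 were higher and 9605 lower under salt in limma's moderated test (80.2% in all), 2740 and 3119 of them at least 2-fold, and 12731 were called and moved the same way in all 5 accessions. Without the array labelled C24 control replicate 1 the counts were 8280 and 9930, and with the slide as a block 8359 and 9880. Within the first scan day, 12 arrays of 4 accessions gave 5131 higher and 6304 lower, and within the second 5445 and 6662. Of the genes called over all arrays, 99.3% had the same direction within each of these days. The arrays of a day are part of the pooled fit, so this agreement is not independent of it. The only C24 control of the first day is the array labelled C24 control replicate 1, so the C24 part of every count within that day, here and below, rests on it. The 2 later scan days held 4 and 2 arrays, too few for a fit. Without the array labelled C24 control replicate 1, Hypoxia under salt was no longer called (camera adjusted p = 0.0841). Camera called 19 of 29 lists, 12 up and 7 down, all with the same sign in both scan days and with the slide block. Over the comparisons within single slides 17 of the 19 kept 1 sign, while the iron deficiency median ran from −2.71 to 1.26 and that of hypoxia from −0.20 to 0.85. The 1.26 is C24 against the array labelled C24 control replicate 1, and the −0.20 is Col. The calls of 7 lists held with an estimated correlation: jasmonate, ethylene, heat shock, flavonoid and anthocyanin, cell wall expansion, cell cycle and DNA replication, and root markers.

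**Figure D2:**
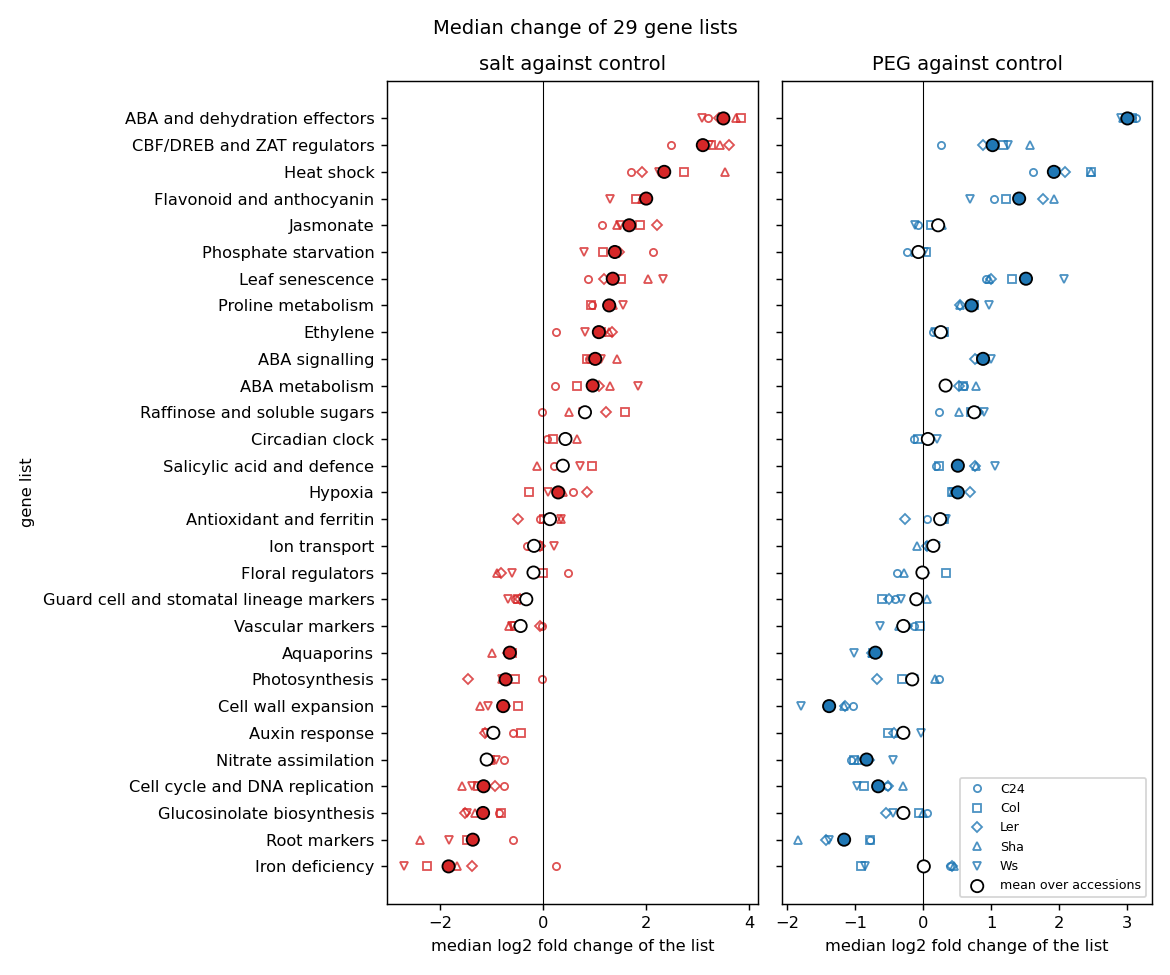
Median log2 fold change of 29 gene lists under salt (left) and PEG (right). Large circles give the mean over 5 accessions, filled where camera called the list (19 under salt, 14 under PEG) and white where it did not, and small open symbols give each accession; the ABA and dehydration effectors lie highest in both panels, at 3.5 and 3.

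PEG raised the same leading ABA genes and lowered growth genes. LTP4 rose by 10.48 ± 0.24 (SE, n = 10 arrays per treatment), RD29B by 7.56 ± 0.27, TSPO by 7.16 ± 0.30, CSLG2 by 7.05 ± 0.19, LEA4-5 by 6.92 ± 0.18 and LEA7 by 6.80 ± 0.13. RAB18 rose by 5.27 ± 0.15 and RD29A by 3.71 ± 0.22. All 32 ABA and dehydration effectors rose (median 3, camera adjusted p = 9.32e-17), as did 17 of 26 ABA signalling genes, with 7 lower (median 0.88, camera adjusted p = 0.00697). HAI1 rose by 5.45 ± 0.16, NCED3 by 2.87 ± 0.11 and CYP707A1 by 2.34 ± 0.11, and PYL6 fell by 4.29 ± 0.07. The ABA metabolism list was not called (8 of 13 higher, 4 lower, median 0.33, camera adjusted p = 0.113).

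Heat shock and flavonoid genes rose under PEG. All 21 heat shock genes were higher (median 1.92, camera adjusted p = 1.66e-11), and 15 of 19 flavonoid and anthocyanin genes (median 1.41, camera adjusted p = 2.7e-05), with PAP1 at 3.09 ± 0.05. P5CS1 rose by 4.22 ± 0.04, and 5 of 9 proline metabolism genes were higher and 2 lower (median 0.71, camera adjusted p = 0.0451, and adjusted p = 0.218 with an estimated correlation). With the slide block, Proline metabolism under PEG was no longer called (camera adjusted p = 0.0766, median 0.70). Leaf senescence genes were higher in 11 of 13 cases (median 1.51, or 1.18 with dim genes at their bounds, camera adjusted p = 0.000142, and adjusted p = 0.218 with an estimated correlation), with SAG13 at 3.65 ± 0.20. Salicylic acid and defence genes rose in 14 of 22 cases (median 0.51, camera adjusted p = 0.00362), among them PR1 (1.82 ± 0.14), PR2 (1.95 ± 0.12) and FMO1 (3.17 ± 0.23). The CBF/DREB and ZAT regulators were higher in 7 of 9 cases (median 1.02, camera adjusted p = 0.0269, and adjusted p = 0.43 with an estimated correlation), with CBF3 at 2.19 ± 0.04. Hypoxia genes rose in 10 of 12 cases (median 0.51, camera adjusted p = 0.0137), with ADH1 at 2.75 ± 0.04.

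Wall, root and division genes fell under PEG. Cell wall expansion genes were lower in 17 of 20 cases (median −1.38, camera adjusted p = 1.57e-05), led by the xyloglucan-modifying enzyme gene XTH6 at −4.09 ± 0.06 and EXPA8 at −3.38 ± 0.16. Cell cycle and DNA replication genes were lower in 22 of 23 cases (median −0.66, camera adjusted p = 1.57e-05), 1 of them at least 2-fold, PCNA1 at −1.08 ± 0.04. Of 14 root markers 12 fell (median −1.16, camera adjusted p = 7.5e-05), with CASP1 at −1.92 ± 0.04 and PRP3 at −2.01 ± 0.11. Aquaporin genes fell in 15 of 19 cases (median −0.70, camera adjusted p = 0.00338, and adjusted p = 0.399 with an estimated correlation), PIP2;4 by 2.3. Nitrate assimilation genes fell in 6 of 7 cases (median −0.83, camera adjusted p = 0.0293, and adjusted p = 0.359 with an estimated correlation), with the nitrate transporter gene NRT1.1 at −1.25 ± 0.05. Among genes with a symbol and above background on at least 8 of 10 arrays of both treatments, the largest falls were CYP712A1 (−7.24 ± 0.05), the MYB-related gene MEE3 (−5.23 ± 0.13), PDF1.2A (−4.65 ± 0.23) and AIR1 (−4.52 ± 0.10). CYP93D1 and CYP76G1, both cytochrome P450 genes, were at least 52.8-fold and 27.4-fold lower and AtMT4a, a metallothionein gene, at least 15.3-fold higher, out of 106 such genes.

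Other lists were not called under PEG. Photosynthesis genes were lower in 10 of 45 cases and higher in 1 (median −0.16, camera adjusted p = 0.339). Jasmonate genes were higher in 14 and lower in 10 of 27 (0.22, 0.295), ethylene genes in 8 and 4 of 14 (0.26, 0.136), and phosphate starvation genes in 4 and 6 of 14 (−0.07, 0.959). Iron deficiency genes were higher in 3 and lower in 6 of 13 cases (0.01, 0.472), with IRT1 at −1.27 ± 0.06 and FRO2 at −1.54 ± 0.11. Ion transport genes gave 15 and 10 of 31 (0.15, 0.268), with NRT1.8 at 3.87 ± 0.12, HKT1 at 0.55 ± 0.16, SOS1 at 0.52 ± 0.09 and NHX1 at 0.48 ± 0.04. Glucosinolate genes gave 6 and 12 of 21 (−0.29, 0.295), and raffinose and soluble sugar genes 7 and 4 of 13 (0.75, 0.132), with GOLS2 at 4.67 ± 0.09. Auxin response genes were higher in 3 and lower in 10 of 15 cases (−0.29, 0.194), antioxidant and ferritin genes in 8 and 5 of 15 (0.25, 0.339) and circadian clock genes in 5 and 3 of 17 (0.07, 0.515). Guard cell and stomatal lineage markers gave 1 and 5 of 12 (−0.10, 0.194), vascular markers 2 and 6 of 8 (−0.29, 0.24) and floral regulators 2 and 4 of 9 (−0.01, 0.821).

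In limma's moderated test 7307 genes were higher and 9226 lower under PEG (75.1% of those tested), 1430 and 2228 of them at least 2-fold, and 12259 were called and moved the same way in all accessions. The counts were 7605 and 9596 without the array labelled C24 control replicate 1, and 7574 and 9550 with the slide as a block. The first scan day alone gave 3623 higher and 4808 lower, and the second 4226 and 5676. Of the genes called under PEG over all arrays, which include those of each day, 99.2% and 99.6% had the same direction within these days. Camera called 14 lists, 9 up and 5 down. Without the array labelled C24 control replicate 1 it called 12, and lost Proline metabolism (camera adjusted p = 0.0614) and Nitrate assimilation (0.0606). All 14 kept their sign in both scan days and with the slide block, and 13 within every slide compared. The calls that held with an estimated correlation were those of 9 lists: ABA and dehydration effectors (adjusted p = 0.0465), ABA signalling (0.0433), salicylic acid and defence, heat shock, flavonoid and anthocyanin, cell wall expansion, cell cycle and DNA replication, hypoxia (0.0416) and root markers (0.0416).

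**Figure D3:**
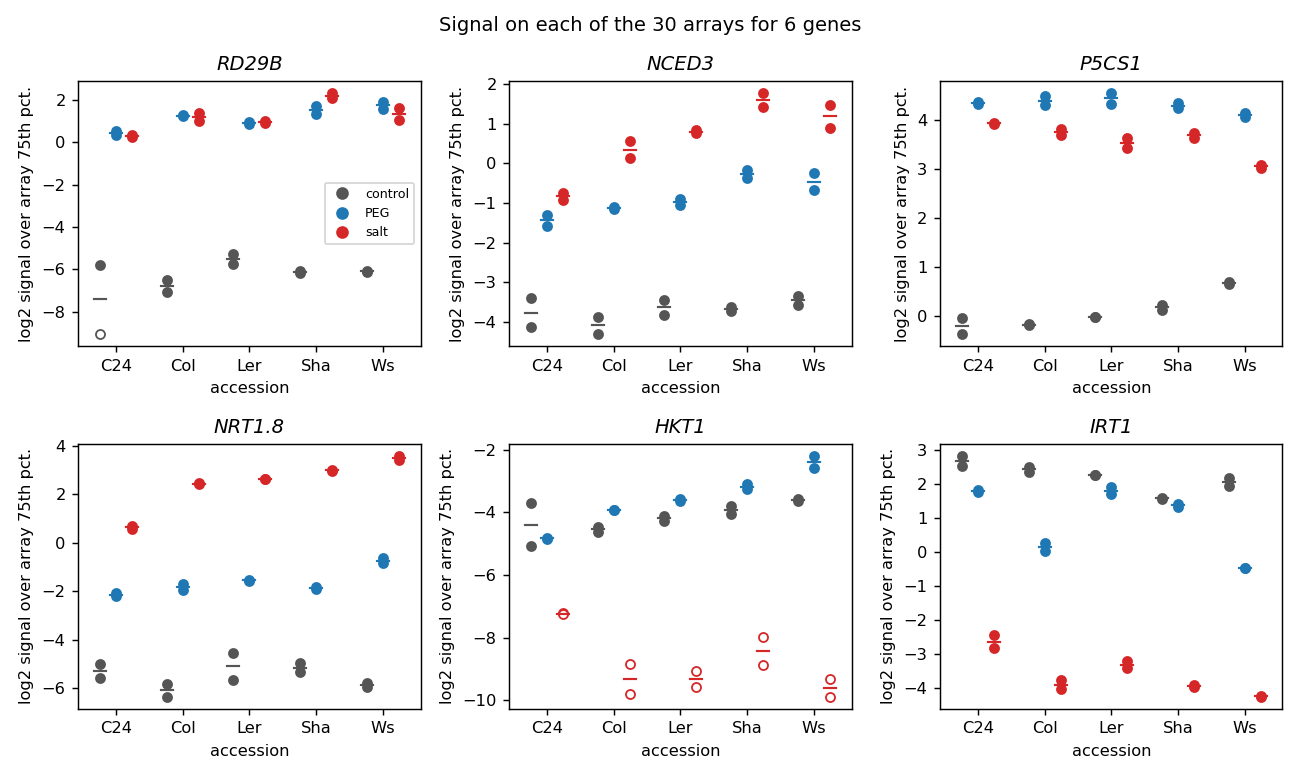
Scaled log2 signal of 6 genes on each of the 30 arrays, by accession (x axis) and treatment (grey control, blue PEG, red salt). Bars mark the mean of 2 replicates and open circles mark arrays where the probe was not well above background; HKT1 lies below background on all 10 salt arrays, and RD29B and P5CS1 rise under both treatments.

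Compared directly, jasmonate, ethylene, CBF/DREB and ZAT, and phosphate starvation genes were higher in salt than in PEG. RRTF1, a redox-responsive transcription factor gene, was 5.19 ± 0.15 higher in salt than in PEG (SE, n = 10 arrays per treatment), NRT2.6 5.16 ± 0.14, BHLH92 5.06 ± 0.34, the acid phosphatase gene PAP14 4.83 ± 0.28, AT4G16820 4.78 ± 0.21 and the beta-glucosidase gene BGLU28 4.66 ± 0.27. RRTF1, NRT2.6 and BHLH92 were above background on 8 and PAP14 and AT4G16820 on 9 of the 10 PEG arrays. Jasmonate genes were higher in salt in 26 of 27 cases (median difference 1.46, camera adjusted p = 3.66e-12), with JAZ5 at 3.27 ± 0.05, and ethylene genes in 13 of 14 (0.74, camera adjusted p = 2.96e-05), with ACS2 at 2.94 ± 0.09. All 9 CBF/DREB and ZAT regulators were higher in salt (2.09, camera adjusted p = 2.96e-05, and adjusted p = 0.246 with an estimated correlation), as were 12 of 14 phosphate starvation genes (1.36, camera adjusted p = 7.66e-05, and adjusted p = 0.245 with an estimated correlation), MGD3, a galactolipid synthase gene, by 3.79 ± 0.10. NRT1.8 differed by 4.06 ± 0.12.

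Salt lay below PEG for iron, glucosinolate, photosynthesis and division genes. IRT1 was lower by −4.54 ± 0.06, CYP82C4 by −3.93 ± 0.29, NAS2 by −3.48 ± 0.08, PCC1, a pathogen-responsive clock-controlled gene, by −3.22 ± 0.13, NCED4, a carotenoid cleavage gene, by −3.18 ± 0.04 and the iron-response regulator gene BHLH101 by −3.16 ± 0.11. HKT1 was at least 16.4-fold lower in salt, while GA20OX5 and the seed storage gene SESA1 were at least 6.49-fold and 3.33-fold higher, out of 93 such genes. Lower lists were iron deficiency (10 of 13, median −1.17, camera adjusted p = 0.00236, and adjusted p = 0.452 with an estimated correlation), glucosinolates (16 of 21, −1.10, camera adjusted p = 7.66e-05, and adjusted p = 0.245 with an estimated correlation), photosynthesis (31 of 45, −0.62, camera adjusted p = 4.83e-05, and adjusted p = 0.557 with an estimated correlation). So were cell cycle and DNA replication genes (20 of 23, −0.50, camera adjusted p = 8.49e-06). Root markers were lower in 9 of 14 cases (−0.31, camera adjusted p = 0.0121, and adjusted p = 0.245 with an estimated correlation). P5CS1 was 0.72 lower in salt than in PEG (−0.72 ± 0.04), and RD29B (0.03 ± 0.27) and RAB18 (−0.02 ± 0.15) differed by less than their errors. These errors use the spread shared over all groups, control arrays included. For RD29B the C24 control arrays stood at −5.77 and −9.05, further apart than the replicates of any salt or PEG group. Its error is therefore not that of the salt and PEG arrays alone.

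Further lists higher in salt were ABA and dehydration effectors (23 of 32, median 0.54, camera adjusted p = 0.000389, and adjusted p = 0.432 with an estimated correlation), flavonoid and anthocyanin (13 of 19, 0.57, camera adjusted p = 0.0155, and adjusted p = 0.242 with an estimated correlation) and cell wall expansion (12 of 20, 0.44, camera adjusted p = 0.0414, and adjusted p = 0.158 with an estimated correlation). With the slide block, Cell wall expansion was no longer called for salt minus PEG (camera adjusted p = 0.0606, median 0.39). The difference was not called for ABA metabolism (median 0.52, camera adjusted p = 0.0606), ABA signalling (0.22, 0.271), proline metabolism (0.24, 0.213), raffinose and soluble sugars (0.06, 0.197) or ion transport (−0.05, 0.673). The same held for aquaporins (0.14, 0.352), leaf senescence (0.51, 0.0922), heat shock (0.00, 0.673) and antioxidant and ferritin genes (0.04, 0.924). Nor was it for auxin response (0.08, camera adjusted p = 0.72), circadian clock (0.19, 0.105), hypoxia (0.41, 0.169) or nitrate assimilation (0.11, 0.924). Vascular markers (−0.15, 0.673), guard cell and stomatal lineage markers (−0.24, 0.165), floral regulators (−0.47, 0.644) and salicylic acid and defence (−0.37, 0.572) were not called either.

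Salt was above PEG for 7428 genes and below it for 7869 in limma's moderated test, and 1858 and 776 differed at least 2-fold, so that 48.6% of all calls but 70.5% of those past 2-fold were higher in salt. Without the array labelled C24 control replicate 1 the counts were 7864 and 8462, and with the slide as a block 7782 and 8318. They were, within the first scan day 2956 and 2613, and within the second 3437 and 3003. Camera called 12 lists, 7 up and 5 down, all of one sign in both scan days, and 3 calls held with an estimated correlation: jasmonate, ethylene, and cell cycle and DNA replication. Adjusted over the list alone, counts of members called matched those over all genes except for photosynthesis (32 lower in salt, 7 lower in PEG), jasmonate (15 higher in PEG, 27 higher in salt than in PEG), circadian clock (4 higher in PEG), guard cell and stomatal lineage markers (0 higher in PEG, 9 lower in salt than in PEG), floral regulators (1 higher in PEG), ABA metabolism (9 higher in salt than in PEG) and salicylic acid and defence (8 higher in salt than in PEG).

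Salt and PEG moved many genes in the same direction. Both raised 5460 genes and both lowered 7235, an overlap of 12695, where independent lists of these sizes would share 2669 and 4027. Both comparisons used the same 10 control arrays. In 20 simulated sets with no effect the overlap was 0, but such sets have few calls to share, so this does not measure what shared controls add. The correlation between the mean changes was 0.49 in those sets, against 0.80 observed across genes. The covariance was 0.936 observed and 0.00848 simulated, a difference of 0.928. With the controls split so that no array served both, the overlap was 12377 and 12274, the correlation 0.77 and 0.76 and the covariance 0.922 and 0.913. Of the shared genes 6169 changed further in salt, 2539 further in PEG and 3987 did not differ by the test. Another 1687 were called in opposite directions, 964 higher in salt and lower in PEG and 723 the reverse, 46 of them at least 2-fold each way.

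Some genes were called under salt, not called under PEG, and differed between the treatments. There were 1397 such genes higher in salt and 1401 lower. BGLU28 rose by 4.36 ± 0.27 under salt against −0.31 ± 0.27 under PEG, HSFA6B, a heat shock factor gene, by 4.67 ± 0.18 against 0.07 ± 0.18, and the syntaxin gene SYP124 by 4.25 ± 0.17 against 0.13 ± 0.17. PCC1 fell by 2.96 ± 0.13 under salt (0.26 ± 0.13 under PEG), AGP30 by 3.37 ± 0.17 (−0.30 ± 0.17) and ACD6, a defence regulator gene, by 3.42 ± 0.22 (−0.37 ± 0.22). NRT2.4, a nitrate transporter gene, was at least 2.26-fold lower in salt than in control. The reverse class, called under PEG without salt, held 925 genes higher and 841 lower. CIPK13, a kinase gene, fell by 3.09 ± 0.21 under PEG (−0.28 ± 0.21 under salt), SULTR1;1, a root sulphate transporter gene, by 2.4 ± 0.25 (0.39 ± 0.25), and CCL, a light-regulated gene, rose by 1.27 ± 0.18 (0.24 ± 0.18). The PEG effect of HSFA6B differed between accessions, from −0.73 in Ler to 1.24 in Ws (interaction adjusted p = 0.0113 by limma's F-test on all arrays), as did that of AGP30, from −1.04 in Sha to 1.42 in Col (0.0087). So did that of NRT2.4, above background on 8 of 10 control arrays, from −1.59 in Ws to 1.48 in Ler (0.0271 by the same test). In C24 the HSFA6B value was −0.97 with the doubtful array and 0.19 without it. Without the array labelled C24 control replicate 1, BGLU28 (−0.65), HSFA6B (0.30) and ACD6 (−0.64) were called under PEG and CCL (0.44) under salt, so these 4 genes leave their class. SQP2, which fell by 2.51 ± 0.49 under PEG, had a salt change of 0.30 ± 0.49 that became −0.32 and was called without the array labelled C24 control replicate 1.

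Within single accessions, among genes with a symbol and above background on all arrays compared, LTP4 led the salt rises in Col, Ler and Sha, DIP2 in C24 and NRT1.8 in Ws. Salt changed 14524 genes in Sha (6833 at least 2-fold), 14111 in Ws, 13864 in Ler, 13287 in Col and 12765 in C24, with 2 arrays against 2 and the spread shared over all groups. PEG changed 12323 in Ws, 12184 in Col, 11713 in Ler, 11649 in C24 and 11434 in Sha. The C24 counts were 5317 and 4043 with array weights, and 3495 and 1853 with only the groups compared in the fit. Without the array labelled C24 control replicate 1 the range was 12738 in C24 to 15697 in Sha under salt and 11473 in C24 to 13729 in Ws under PEG. LTP4 rose under salt in Col (11.53 ± 0.54, SE, n = 2 arrays per group), Ler (10.34 ± 0.54) and Sha (11.79 ± 0.54), and its value in Ws was 9.34. In C24 it was 12.55 with the doubtful array and 14.07 without it, the latter against a single control array not above background. DIP2 rose by 8.20 ± 0.29 in C24 (8.54 without the doubtful array) and NRT1.8 by 9.36 ± 0.26 in Ws. By the same limit CYP712A1 fell furthest under PEG in all 5 accessions, from −6.74 ± 0.10 in Ler to −7.95 ± 0.10 in Ws. The largest salt falls within that limit were CYP712A1 in C24 (−5.81 ± 0.10) and Ler (−5.59 ± 0.10), CYP82C4 in Col (−6.49 ± 0.65), ATCSLB05, a cellulose synthase-like gene, in Sha (−5.58 ± 0.27) and IRT1 in Ws (−6.31 ± 0.13).

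The salt response differed between accessions for 12339 genes and the PEG response for 8423 (limma's moderated F-test of the accession by treatment interaction), and 5922 and 3579 of these had effects at least 2-fold apart. WRKY28 rose by 1.92 in C24 and 5.18 in Ws under salt (adjusted p = 1.71e-12) and MAPKKK21 by 2.43 in C24 and 6.92 in Ler (1.19e-11). The values were, for MAPKKK19, 1.90 in C24 and 6.72 in Ler (1.32e-11), CYP94B3, a jasmonate-degrading enzyme gene, 2.81 in C24 and 6.81 in Ws (1.32e-11), and WRKY40 2.00 in C24 and 4.86 in Col (1.48e-11). The C24 values of these 5 genes were 1.93, 2.35, 1.95, 2.71 and 1.97 without the doubtful array. Under PEG the camalexin synthesis gene PAD3 changed from −0.26 in Col to 2.45 in Ws (adjusted p = 1.71e-10), CCD8, of strigolactone synthesis, from −1.42 in C24 to 3.15 in Ler (1.54e-10) and XTH24 from −2.83 in C24 to −0.02 in Ws (1.54e-10). M17, a late embryogenesis gene, was at least 51.4-fold higher under PEG in C24, where no control array was above background, against −0.89 on the log2 scale in Col (1.94e-12). CYP705A23 was at least 42.9-fold higher under PEG in Ws, against −0.52 on the log2 scale in Col (1.27e-11). The interaction counts were 14262 and 11121 without the array labelled C24 control replicate 1, 14770 and 10173 with the slide as a block, and 4520 and 2269 with array weights, which gave both C24 control arrays a weight of 0.09.

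**Figure D4:**
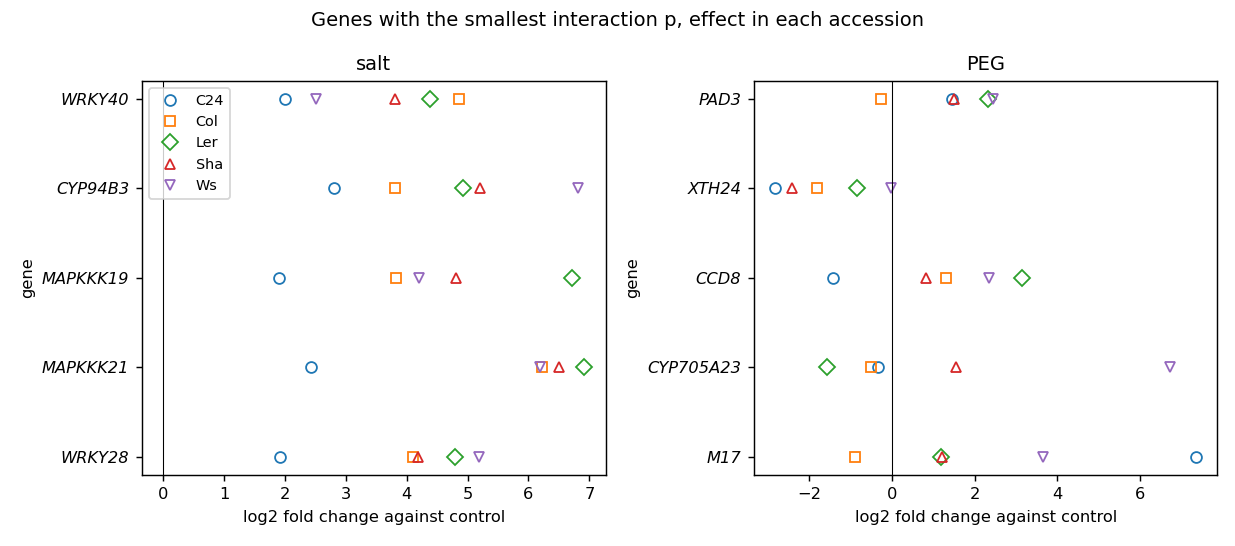
Log2 fold change in each accession for the 5 genes with the smallest interaction p, among genes with a symbol, under salt (left) and PEG (right), 2 arrays per group. Each open symbol is 1 accession, C24 has the smallest salt effect for all 5 genes on the left (1.90 to 2.81), and M17 and CYP705A23 include arrays not well above background.

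Under control conditions 15157 genes differed between accessions by limma's moderated F-test. TEX1, a component of an RNA export complex, had scaled log2 signals of 0.23 to 0.36 in C24, Col, Ler and Sha and −6.98 in Ws (adjusted p = 7.14e-18), and AER, an alkenal reductase gene, −0.20 to 0.34 against −3.60 in Ws (8.05e-16). IGMT2, an indole glucosinolate methyltransferase gene, stood at −1.85 in Col and 1.11 to 1.37 elsewhere (1.23e-15). PAP24 was above background in the controls of Col, Sha and Ws and not in those of C24 and Ler (1.15e-15), and M17 in those of Col and Sha alone (1.11e-15). The probes match the sequence of the array design, and a sequence difference under a probe lowers its signal, so these are differences of signal that need not be differences of expression. The count was 17260 without the array labelled C24 control replicate 1, 12699 with the slide as a block, 4024 with array weights and 7549 with only the control arrays in the fit.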

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

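The position and slide tests of the first pattern, the tests without C24 and with the slide block and the opposite-direction test of the second, and the scaling test of the third were chosen after the result was seen.

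The first pattern is the array labelled C24 control replicate 1, whose replicate difference had an SD of 1.08 over genes where the other groups had 0.31 to 0.43. On 776 genes at least 4-fold apart between the replicate 2 arrays of C24 and Ler under PEG and salt, it lay at 0.92 between C24 (0) and Ler (1), beside 0.88 and 0.92 for the Ler controls and −0.05 for C24 control replicate 2, and RNA of Ler control plants under a C24 label is a candidate explanation. A mixture with C24 RNA is argued against by 68 genes high in C24 and low in Ler, whose C24 share had a median of −0.00153 (quartiles −0.00511 and −0.000426). An effect of its slide is argued against by the treated C24 arrays of that slide, the higher of which lay at 0.004. No array labelled Ler, apart from those that set the scale, lay near C24, where the sample came from stays open, and no biological explanation was tested because the design gives none.

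The second pattern is the number of genes whose response differed between accessions: 12339 under salt and 8423 under PEG by the interaction test, of which 1794 and 1129 were called higher in 1 accession and lower in another. Over the 4 accessions without C24 the salt count was 12156 (10076 for PEG), so the doubtful array alone does not account for it, and with the slide as a block it was 14770. Probe mismatches could account for part of it. The accession with the smallest effect was also the dimmest for 37.4% of the genes under salt and 34.0% under PEG, where an even spread over accessions gives 20%. Brightness was the higher of the control and treated means, so a smaller rise by itself makes an accession dimmer. The share can therefore pass 20% without any mismatch, and mismatch and a true difference of response cannot be told apart for these genes. For genes with opposite directions a mismatch would have to turn a fold change, and without C24 there were still 152 genes called at least 2-fold each way under salt (108 under PEG). Whether a mismatch can do so was not tested, since the genomes of the accessions were not at hand. No expected count was set beside these, so they do not exclude mismatch. A difference in response between the accessions, which the design names, stays open as a hypothesis.

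The third pattern is the fall of root markers, given that the labels name both whole seedlings and leaves. A smaller share of root RNA in treated samples would lower all 14 markers by about the same factor, but the share within 0.5 (log2) of their median was 21.4% under salt and 28.6% under PEG, with changes from −0.41 to −2.28 and from −0.06 to −2.01. For scaling of the arrays, the median of the markers less that of all genes was −1.31 under salt and −1.10 under PEG. The arrays were already scaled, with medians of all genes of −0.058 and −0.061, so subtracting these could hardly move the markers. The values show only that the markers fell relative to other genes, as camera did, which a shift of whole arrays would not give. A change of root gene activity, or a root share that changed together with it, may remain, and the iron uptake and ion transport genes of the root are open to the same doubt.

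The genes with the strongest tests of a difference between accessions, among those with a symbol, had the following ranges of effect on the log2 scale. Under salt these were 3.26 for WRKY28, 4.48 for MAPKKK21, 4.82 for MAPKKK19, 4.00 for CYP94B3 and 2.86 for WRKY40. Under PEG they were 8.25 for M17, 8.30 for CYP705A23, 4.57 for CCD8, 2.81 for XTH24 and 2.71 for PAD3. The ranges of M17 and CYP705A23 rest on arrays not well above background, where the bounds are rises of at least 51.4-fold for M17 in C24 and 42.9-fold for CYP705A23 in Ws.

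Probes without a locus, which the main comparisons left out, also carried signal: of 5361 tested, 1750 were higher and 1510 lower under salt, and 1317 were higher and 1272 lower under PEG.

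Other splits of the treatment labels within accessions bear on the counts. In 100 splits, the real one included, 1 gave as many genes for salt against control (17643, highest other 12729), 1 for PEG against control (16533, highest other 10063), 1 for salt against PEG (15297, highest other 9654) and 1 for the overlap (12695, highest other 68). No other split drawn reached these counts, and 100 splits can show no share below 1 in 100. For the overlap all 3 labels were shuffled, which removes both treatment effects. That test therefore cannot tell whether salt and PEG calls coincide more than their sizes imply. The highest other splits of the 3 treatment comparisons kept 3 accessions intact, a structure of the samples that calls many genes.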

How the results depend on the processing

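Of the alternatives reported here, the probes without a locus were chosen after seeing the data. Of 370 effects of named genes, which were mostly chosen for size or p, 28 changed their side of the threshold or their direction under any setting, and 87 list results gave 35, most often with an estimated correlation in camera. Except for the settings named below, which include the refits within 1 scan day, each count of genes stayed within 1.5 times its value, and the cause of a larger move was not tested unless stated. Refits within 1 scan day are of another form, with 12 arrays, 4 accessions, accession and treatment terms alone and 6 residual degrees of freedom, and gave fewer calls: for salt against PEG 2956 higher and 2613 lower on the first day, where all arrays gave 7428 and 7869. A direction reversed for SQP2 under salt, −0.32 without C24 control replicate 1 (0.30 with all arrays, 0.92 without C24 control replicate 2), and for HSFA6B under PEG, −0.16 without C24 control replicate 2 (0.07), and neither was called with all arrays. Normexp background gave 4960 genes with a PEG interaction. Array weights gave 5317 genes changed by salt and 4043 by PEG in C24, 4520 and 2269 interaction genes and 4024 control differences, and the fit of only the groups compared gave 3495 and 1853 in C24 and 7549 control differences. A 2-fold minimum, which can only remove calls, left 2740 higher and 3119 lower under salt, 1430 and 2228 under PEG, 1858 and 776 for salt against PEG and an overlap of 2844. It left 4715, 5624, 6099, 6833 and 6363 genes under salt and 3626, 4043, 3644, 3878 and 4485 under PEG in C24, Col, Ler, Sha and Ws. Lists called were 7, 9 and 3 with an estimated correlation (salt, PEG, salt against PEG) and 28, 25 and 25 with fry, which tests a different question.

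Leaving out 1 array at a time, with the lone array of its group assumed to vary like the others, gave 7883 to 8388 genes higher and 9447 to 9930 lower under salt, 7129 to 7792 and 9021 to 9606 under PEG, 7200 to 7864 and 7648 to 8462 for salt against PEG, and an overlap of 12440 to 13417. Only the PEG interaction moved by over 1.5 times, from 7087 without C24 PEG replicate 2 to 12679 without C24 control replicate 2. The salt interaction had 10967 to 15104 genes. The replicate numbers were not taken to pair the samples, because that required a correlation over 0.1 between the deviations of every pair, and 11 of 15 reached it, in a range of −0.05 to 0.36. The values of −0.05 were those of the C24 control with C24 PEG and salt, which hold the doubtful array. The other pairs below the limit were in Ler, at 0.09 and 0.07. The replicates of each group lay on different slides and scan days, so replicate number is tied to both. With a replicate block within accession 8313 genes were higher and 9889 lower under salt, 7642 and 9589 under PEG, 7728 and 8322 for salt against PEG, with 14412 and 10936 interaction genes and 19, 13 and 11 lists. The block ended the list calls of proline metabolism under PEG (median 0.71) and cell wall expansion for salt against PEG (0.44). Dim genes carry the least: signals near background have only bounds, and the median of all genes stayed within 0.1 of 0 under all scalings.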

Other observations

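The tests of lists by accession given here were chosen after the result was seen, and the control levels were picked for their size.

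Single genes with a wide range of control signal between accessions are given here, out of 15157 that differed, and no list was tested for it. The scaled log2 signal of PR1, a marker of salicylic acid defence, was 1.17 in Ler, 0.07 in C24 and −4.99 in Col (limma adjusted p = 1.09e-10 for accession differences), and that of PR2 was 1.88 in Ler and −2.48 in Col (5.99e-10). FLC, the repressor of flowering, stood at −1.03 in Ws, −2.61 in Col, −6.37 in Ler and −6.86 in Sha (limma adjusted p = 0.00994). Genes of the jasmonate-responsive storage proteins VSP1 and VSP2 were highest in Ws (3.33 and 3.11) and lowest in Ler (−0.65 and −0.97). The iron-response regulator genes BHLH38, BHLH39, BHLH100 and BHLH101 were highest in Ws, at 1.73, 0.12, 1.43 and 0.76. CAT3, a catalase gene, was at 0.52 in Ws and 4.50 to 5.26 elsewhere (limma adjusted p = 2.6e-10), and TGG2, a myrosinase gene of guard cells, at 4.23 in Col and −3.26 in Sha (limma adjusted p = 0.000175). Heat shock genes that were dim in some control arrays had wide ranges too, such as APX2 with 5.24 (above background on 7 of 10 control arrays). The size of such a range is not exact, because signals near background have only bounds. C24 means include the array labelled C24 control replicate 1, and probe sequence differences were not ruled out for any of these genes.

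Lists also responded unequally between accessions. Camera on the effect in 1 accession less the mean of the other 4 called 92 of 290 tests, and 27 with an estimated correlation. Under PEG the root markers had a median of −1.83 in Sha and −0.92 elsewhere (camera adjusted p = 0.0163 with an estimated correlation), and the flavonoid and anthocyanin genes 1.92 in Sha against 1.26 and 0.69 in Ws against 1.58 (camera adjusted p = 0.0163 with an estimated correlation for each). Under salt the jasmonate genes had a median of 2.2 in Ler against 1.69, and the ethylene genes 0.25 in C24 against 1.28 (camera adjusted p = 0.0163 with an estimated correlation for each); the C24 ethylene median was 0.24 without the array labelled C24 control replicate 1. Photosynthesis genes under salt had a median of −1.47 in Ler against −0.53 (camera adjusted p = 3.19e-09, and adjusted p = 0.537 with an estimated correlation). Leaving out the doubtful array moved the C24 medians of photosynthesis genes under salt from −0.02 to 0.42 and of iron deficiency genes from 0.24 to −0.74.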
